A study of Mus musculus with 20 samples.

How the data were processed

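Gene expression was measured in the livers of 20 mice with 1 Affymetrix array per liver. The labels place 5 mice, described as biological replicates, in each of 4 groups: fed WT, fasted WT, fed Mcl1(L-/-) and fasted Mcl1(L-/-). Mcl1(L-/-) is the deposited name of the genotype called Mcl1KO. Per the labels' protocols, total RNA was isolated with Trizol and double-stranded cDNA was made with the GeneChip WT PLUS kit. The authors deposited 1 table of normalised log2 signals, made by RMA (robust multi-array average, which corrects background, quantile-normalises and summarises probes into probe sets) and Partek 7.0, per the submitters' processing notes. The RMA settings, the annotation version and the array's probe positions are not given in the sources used here. The table does not state its log base. Values from 1.34 to 12.56 and the use of RMA fit a log2 scale, which is assumed for every fold change. RMA quantile-normalises the arrays to a common distribution, so a shift shared by most transcripts would not be visible, and it compresses the folds of dim probe sets. The 20 array medians lay between 3.35 and 3.47. No 2 arrays held identical values.

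Of the 22206 probe sets, 19572 carried 1 gene symbol in the platform annotation, 0 carried several and 2634 carried none. Probe sets without a symbol stayed in the tests and were not named. These symbols covered 19505 genes, of which 55 had several probe sets. The probe set with the highest mean over all arrays stood for such a gene. Among genes named in the text the probe sets of Nudt7 differed in whether they were called, for fasting in WT. A table of RefSeq genes that names the assembly GRCm38.p6 was used for gene names and for which genes neighbour each other. Its coordinates are not printed, because the build behind the array annotation is not given in the sources used here.

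Differences were tested with limma 3.58.1 in R 4.3.3 on the log2 signals. A model with 1 mean per group was fitted to all 20 arrays, so that the 4 groups shared 1 estimate of the spread, moderated by eBayes (prior df 6.95). Contrasts were fasted minus fed within each genotype, Mcl1KO minus WT within each feeding state, and the interaction, which is the fasting effect in Mcl1KO minus that in WT. P-values were adjusted by the Benjamini-Hochberg method over all probe sets, and a probe set was called at an adjusted p under 0.05. A positive log2 value means higher in fasted or in Mcl1KO livers. Standard errors (SE) come from the model, with n = 5 mice per group throughout. They assume the same spread in all 4 groups. Fasted Mcl1KO livers varied more for some genes, such as Lepr (standard deviation 2.29, against 0.36 to 0.62 in the other groups). For such genes the SE and adjusted p of comparisons with fasted Mcl1KO livers can be too small. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

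Gene lists were tested with camera, limma's competitive set test, at a preset inter-gene correlation of 0.01. It compares a list's members with all other genes on the array. There were 47 lists, of pathways, stress responses, hepatocyte zones and markers of other cell types of the liver or its neighbours. They held 919 symbols, of which 819 (89.1%) were measured. A list of sex-linked genes was left out of the tests, leaving 46, adjusted together. Each list was also tested with a correlation estimated from the arrays, on ranks, and with fry, which asks whether the genes of a list move one way without comparing them with other genes.

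The tests, the lists, the alternatives and the rule for naming genes were fixed before the data were examined, except those said below to be chosen later. For each contrast that rule took the 10 called genes with the largest rise and the 10 with the largest fall. For the 4 pairwise contrasts it also required that all 5 arrays of 1 group lay on the same side of all 5 of the other. Predicted or unnamed gene models were skipped. For each list it took up to 3 called members in each direction, or up to 2 members with the largest difference where none was called. Mcl1 was always named. Genes outside the rule are said to be so.

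The steps were tested on simulated data with 200 changed probe sets among 22206. The simulated noise was normal, independent between probe sets and of equal spread in all groups, so rates in the real arrays can differ. For the fed comparison of genotypes, a log2 change of 1 was recovered in 91.0% of probe sets and one of 0.5 in 38.8%, with 10 false calls. In the interaction, the same sizes were recovered in 71.6% and 13.4%, with 3 false calls. Fasting in WT gave 92.5% and 35.8%, fasting in Mcl1KO 98.5% and 43.3%, and the fasted comparison of genotypes 91.0% and 40.3%. The number of arrays limits the precision, and the interaction, whose median SE was 0.190 against 0.135 for the other contrasts, is the least precise.

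Alternatives were other scalings, moderation and array weights, a filter on dim probe sets, a required fold, fits on the compared groups alone, the replicate number as a block and leaving out each array in turn. Probe sets at or below the 33rd percentile of mean signal, which lay at 2.66, are called dim.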

Results

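The series asks how fasting changes gene expression in livers with and without Mcl1, which encodes an anti-apoptotic member of the BCL2 family. Liver RNA of 20 mice was hybridised, with 5 mice in each of 4 groups. Mice had food at all times or were kept for 48 h in wire-bottom cages without food, with water always available. In Mcl1(L-/-) mice, referred to as Mcl1KO, the floxed gene was deleted in the liver by an adeno-associated virus carrying Cre recombinase. What the WT mice received is not given in the sources used here, so a response to virus or Cre cannot be told apart from one to the loss of Mcl1. For some named genes 1 array stood apart from its group, most often fed WT replicate 1 (7 genes), and fasted WT replicate 4 and fed Mcl1KO replicate 2 (5 genes each). Arrays of the same group correlated at r = 0.979 to 0.990 across probe sets, and arrays of different groups at 0.958 to 0.989. The first principal component held 49.3% of the variance and placed all 10 fed livers below all 10 fasted livers. The second held 10.8%. Fasted Mcl1KO replicates 1 to 5 lay at 38.5, 42.8, 17.4, 25 and 39.6 on the first and at -13.5, -18.8, 6.41, -4.47 and -13.7 on the second, where fasted WT livers lay at 6.56 to 17.1 and at 14.2 to 18.9.

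Mcl1 transcript was lower in every Mcl1KO liver than in every WT liver. Its log2 signal was 7.43 ± 0.15 (SD, n = 5) in fed WT, 7.28 ± 0.09 in fasted WT, 6.09 ± 0.16 in fed Mcl1KO and 6.14 ± 0.25 in fasted Mcl1KO livers. The 5 fed WT arrays gave 7.46, 7.52, 7.29, 7.25 and 7.60, and the 5 fasted WT arrays 7.25, 7.16, 7.25, 7.41 and 7.33. The fed Mcl1KO arrays gave 6.24, 5.83, 6.05, 6.17 and 6.14, and the fasted Mcl1KO arrays 6.18, 6.19, 5.88, 5.94 and 6.50. The Mcl1KO signal was 39.5% of WT with food (log2 -1.34, SE 0.12, limma adjusted p = 5.07e-07) and 45.4% in the fast (log2 -1.14, adjusted p = 4.47e-06). The difference between fasted and fed was -0.15 in WT (adjusted p = 0.595) and 0.05 in Mcl1KO livers (adjusted p = 0.863). Which exons the probe set covers is not given in the sources used here, so the remaining signal is no measure of undeleted cells.

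**Figure D1:**
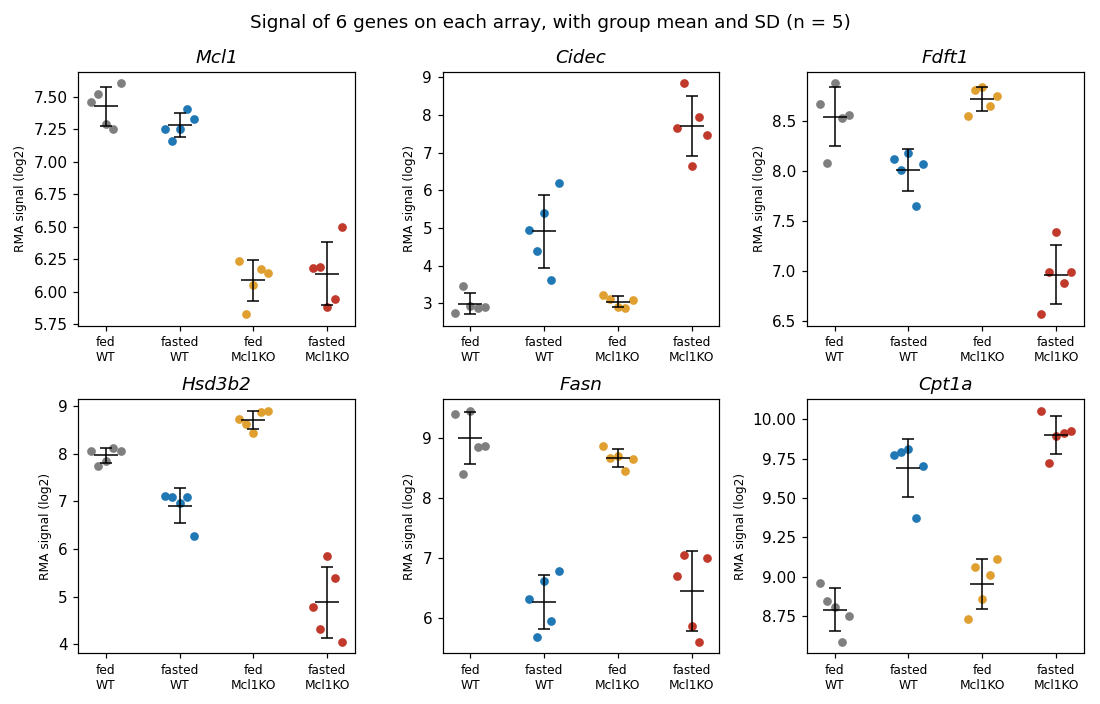
RMA signal (log2) of 6 genes on each of the 20 arrays, by group, with the group mean and SD (n = 5). Mcl1 lies between 5.83 and 6.50 in Mcl1KO livers and between 7.16 and 7.60 in WT livers, and Cidec, Fdft1 and Hsd3b2 are among the genes whose fasting response differed between genotypes.

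In WT livers, fasting lowered genes of de novo lipogenesis and the interferon response and raised genes of amino acid catabolism and gluconeogenesis. The largest fall was that of Hsd3b5, a male-biased hydroxysteroid dehydrogenase, at 47.2-fold (log2 -5.56, SE 0.18, adjusted p = 6.6e-16). Slco1a1, an organic anion transporter, fell 12.3-fold, the carbonic anhydrase gene Car3 fell 8.96-fold and the cytochrome gene Cyp1a2 fell 8.58-fold (adjusted p = 6.6e-06, 1.93e-05 and 1.73e-08). Cdkn1a, a cell cycle inhibitor, rose 14.5-fold (log2 3.86, SE 0.44, adjusted p = 2.35e-06), and Cyp17a1, a steroid hydroxylase, rose 12.4-fold (adjusted p = 2.4e-05). Apoa4, an apolipoprotein, rose 7.98-fold and Mfsd2a, a transporter of lysophosphatidylcholine, 5.79-fold (adjusted p = 2.11e-07 and 1.5e-06). Limma called 1507 of 22206 probe sets, 689 higher and 818 lower, and 336 of them changed at least 2-fold. In 1634 probe sets (7.36%) the fed and fasted arrays did not overlap, against 0.794% by chance.

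Of 20 measured genes of de novo lipogenesis, 14 fell and 0 rose with fasting in WT (17 fell adjusted over the list alone; camera adjusted p = 7.66e-29). Scd1, the desaturase of stearate, fell 6.98-fold, Thrsp 6.74-fold, and the elongase gene Elovl6 and the fatty acid synthase gene Fasn 6.60-fold each. Of 19 cholesterol synthesis genes 14 fell (16 adjusted over the list alone; adjusted p = 5.65e-18, and adjusted p = 0.053 with an estimated correlation). Among them the cholesterol carrier gene Stard4 fell 5.06-fold, Nsdhl 4.52-fold, with 5.0 in fasted WT replicate 4 against 7.03 to 7.63 in the other fasted WT livers, and Sqle, the squalene epoxidase gene, 3.48-fold. Mitochondrial beta-oxidation had 10 of 20 members higher and 0 lower (13 higher adjusted over the list alone; adjusted p = 1.27e-10, and adjusted p = 0.119 with an estimated correlation). Cpt1a, the carnitine palmitoyltransferase that admits fatty acids to mitochondria, rose 1.87-fold, Acadm 1.83-fold and Slc25a20 1.71-fold. Targets of the fatty acid receptor PPARα had 11 of 24 members higher and 1, Fabp1, lower (13 and 2 adjusted over the list alone; adjusted p = 4.87e-07, and adjusted p = 0.190 with an estimated correlation). Among them the lipid droplet gene Cidec rose 3.78-fold. Cyp4a14 rose 4.22-fold (adjusted p = 0.041), with 8.04 in fed WT replicate 1 against 9.93 to 10.2 in the other fed WT livers. That call was lost when any 1 of the 10 WT arrays was left out, with trend and robust moderation and with the ordinary model, and the highest adjusted p over its alternatives was 0.127. Peroxisomal beta-oxidation had 3 of 20 members higher and 1 lower (7 and 1 adjusted over the list alone; adjusted p = 0.00964, and adjusted p = 0.414 with an estimated correlation), a list call lost without fasted WT replicate 1 (adjusted p = 0.0677). Its carnitine acetyltransferase gene Crat rose 3.40-fold (SE of log2 0.17).

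Urea cycle and amino acid catabolism genes had 12 of 24 members higher and 0 lower (17 higher adjusted over the list alone; adjusted p = 5.67e-16), with Got1 up 3.66-fold and Asl, the argininosuccinate lyase gene, up 2.93-fold. In gluconeogenesis 9 of 17 members rose and 1 fell (10 and 1 adjusted over the list alone; adjusted p = 1.18e-09), with the coactivator gene Ppargc1a up 3.48-fold. Both lists kept their calls with an estimated correlation (adjusted p = 0.0421 and 0.027). Glucocorticoid targets had 6 of 14 members higher (9 adjusted over the list alone; adjusted p = 1.40e-10, and adjusted p = 0.053 with an estimated correlation), including Zbtb16 at 5.98-fold and Fkbp5 at 4.23-fold. Interferon response genes had 9 of 23 members lower (11 adjusted over the list alone; adjusted p = 1.76e-11), with Ifit3 down 2.72-fold and Irf7 down 2.61-fold. Markers of Kupffer cells, the resident macrophages of the liver, had 7 of 16 members lower (12 adjusted over the list alone; adjusted p = 4.36e-13), with Cd5l down 2.82-fold, Lyz2 2.78-fold and Folr2 2.76-fold. Hepatocyte markers had 3 members higher and 1 lower of 18 (5 and 1 adjusted over the list alone; adjusted p = 0.235), and lymphocyte markers had 0 of 18 called over all genes or adjusted over the list alone (adjusted p = 0.471). Exocrine pancreas markers had 0 of 13 called (0 adjusted over the list alone) with a list adjusted p of 0.0307 (and adjusted p = 0.421 with an estimated correlation). The former became 0.384 without fasted WT replicate 1 and 0.0635 without fed WT replicate 2. In total 28 of 46 lists were called, 6 of them with an estimated correlation. Random splits of the same 10 arrays called a median of 8 lists and at most 23. Each of these splits leaves unequal numbers of fed and fasted arrays on its 2 sides, so part of the fasting difference remains in it. The counts are therefore no rate of false list calls. A single list with an adjusted p near 0.05 has little weight, since most list calls were lost with an estimated correlation. No called list turned its direction under either rescaling of the arrays, in any of the 5 comparisons.

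In Mcl1KO livers, fasting lowered genes of cholesterol and fatty acid synthesis and the interferon response, and raised PPARα targets, lipid droplet genes, ribosome biogenesis genes and genes of the mitochondrial unfolded protein response. Hsd3b5 again fell most, by 49.8-fold (log2 -5.64, SE 0.18, adjusted p = 4.86e-16), followed by Car3 at 47.2-fold, Sqle at 19.5-fold, with 4.14 in fasted Mcl1KO replicate 3 against 2.51 to 2.89 in the others, and Cyp1a2 at 17.6-fold. Cidec, which encodes a lipid droplet protein that promotes droplet fusion, rose 25.3-fold (log2 4.66, SE 0.35, adjusted p = 2.47e-09). Cyp17a1 rose 22.8-fold, the oestrogen sulfotransferase gene Sult1e1 19.6-fold, Lepr, the leptin receptor gene, 14.2-fold (log2 3.83, SE 0.66, and 4.49 without fasted Mcl1KO replicate 4), Cdkn1a 14.0-fold and Rab30 12.7-fold. Cyp4a14 rose 11.1-fold, Cyp4a31 9.12-fold and the thioesterase gene Acot1 9.04-fold (adjusted p = 0.000267, 7.43e-08 and 1.08e-06). For Cyp4a14 fed Mcl1KO replicate 1 had 4.84 against 7.98 to 9.80 in the others, and without it the log2 change of 3.47 was 2.58. Inmt and Hsd3b2 fell 14.2-fold each and Cyp2c70, a bile acid hydroxylase, fell 12.9-fold. Limma called 3208 probe sets, 1821 higher and 1387 lower, of which 668 changed at least 2-fold. Fed and fasted arrays did not overlap in 2276 probe sets (10.2%, against 0.794% by chance).

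All but 1 of the 19 cholesterol synthesis genes fell in fasted Mcl1KO livers, which is 18 both over all genes and adjusted over the list alone (median log2 -1.80, camera adjusted p = 1.64e-29). Examples are Nsdhl at 11.4-fold, Idi1 at 10.3-fold and Stard4 at 9.81-fold. De novo lipogenesis had 14 of 20 members lower and 1 higher (14 and 1 adjusted over the list alone; adjusted p = 1.99e-16), with Fasn down 4.64-fold and Scd1 down 6.87-fold. Among PPARα targets 15 of 24 rose and 2 fell (17 and 2 adjusted over the list alone; adjusted p = 4.15e-15). Ribosome biogenesis genes had 15 of 28 members higher and 0 lower (19 higher adjusted over the list alone; adjusted p = 6.33e-11), including the nucleolar genes Ddx21 at 2.13-fold and Nop58 at 2.08-fold. The mitochondrial unfolded protein response had 10 of 14 members higher (10 adjusted over the list alone; adjusted p = 1.11e-07), with the protease subunit gene Clpx at 2.63-fold. Subunits of respiratory complexes II to V had 23 of 38 members higher (28 adjusted over the list alone; adjusted p = 3.23e-12, and adjusted p = 0.0835 with an estimated correlation), with the cytochrome c gene Cycs at 1.59-fold. Complex I had 16 of 36 higher (18 higher and 1 lower adjusted over the list alone; adjusted p = 5.55e-08, and adjusted p = 0.0835 with an estimated correlation). The citric acid cycle had 9 of 18 higher (11 adjusted over the list alone; adjusted p = 2.49e-06, and adjusted p = 0.0835 with an estimated correlation), with Fh1, the fumarase gene, at 1.97-fold. Mitochondrial beta-oxidation had 12 of 20 higher (16 adjusted over the list alone; adjusted p = 5.20e-13, and adjusted p = 0.0698 with an estimated correlation), with Acadm at 2.09-fold and Hadhb at 1.96-fold.

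Lipid droplet genes had 9 of 22 members higher and 1 lower in fasted Mcl1KO livers (9 and 2 adjusted over the list alone; adjusted p = 0.000229, and adjusted p = 0.00853 with an estimated correlation), with Fabp4, a fatty acid carrier, at 6.27-fold and Plin5 at 4.24-fold. Interferon response genes had 16 of 23 lower (19 adjusted over the list alone; adjusted p = 5.56e-16), including Bst2 at 3.46-fold. Cell cycle genes had 6 of 30 lower (11 adjusted over the list alone; adjusted p = 1.86e-06), with Ccnb2 down 2.10-fold. The proliferation marker Mki67 fell 2.31-fold (log2 -1.21), with 5.78 in fed Mcl1KO replicate 2 against 3.26 to 3.66 in the other fed Mcl1KO livers, and a log2 change of -0.75 without that array. Of 18 clock genes 3 rose and 8 fell (3 and 9 adjusted over the list alone; list adjusted p = 0.0884). Arntl rose 4.99-fold, Dbp fell 6.61-fold and Per3 fell 3.47-fold. Acute phase genes had 4 of 24 higher and 10 lower (4 and 11 adjusted over the list alone; adjusted p = 0.00264, and adjusted p = 0.250 with an estimated correlation), with Saa2, a serum amyloid gene, down 9.49-fold. Markers of Kupffer cells had 1 of 16 higher and 6 lower (1 and 8 adjusted over the list alone; adjusted p = 0.00882, and adjusted p = 0.265 with an estimated correlation), a list call lost without fasted Mcl1KO replicate 3 (adjusted p = 0.0551). Hepatocyte markers had 4 of 18 higher and 3 lower (5 and 4 adjusted over the list alone; adjusted p = 0.595). In total 31 of 46 lists were called, 11 of them with an estimated correlation.

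The fasting responses of the genotypes overlapped. Of the 1507 probe sets called in WT, 1012 were also called in Mcl1KO livers, 1011 (67.1% of the 1507) in the same direction and 1 in the opposite. Of the former, 467 were higher in both and 544 lower in both, where 56.5 and 51.1 would be shared by independent lists. Across probe sets the fold changes correlated at r = 0.68 (Spearman rho 0.41), with no arrays in common. Genes of similar response in both genotypes include Cpt1a (1.87-fold in WT and 1.93-fold in Mcl1KO), Fkbp5 (4.23-fold and 4.44-fold), Scd1 (6.98-fold and 6.87-fold lower) and Apoa4 (7.98-fold and 8.82-fold). Their interaction estimates were 0.05, 0.07, 0.02 and 0.14 on the log2 scale, with SE of 0.15, 0.23, 0.26 and 0.41. These errors do not exclude moderate differences.

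The interaction contrast tests whether fasting acted differently with and without Mcl1. Hsd3b2, a hydroxysteroid dehydrogenase gene, fell 2.08-fold on fasting in WT and 14.2-fold in Mcl1KO (interaction log2 -2.77, SE 0.34, adjusted p = 0.000329). It lies within 200 measured genes of Mcl1 on the same chromosome. Rab30, a small GTPase of the Golgi, rose 12.7-fold in Mcl1KO and measured 1.54-fold in WT (adjusted p = 0.433; 6.91 in fed WT replicate 2 against 5.08 to 5.52 in the others), with an interaction of 3.04 (SE 0.53, adjusted p = 0.022). Cidec rose in both, 3.78-fold and 25.3-fold, with an interaction of 2.74 (SE 0.50, adjusted p = 0.022). Fdft1, the squalene synthase gene, fell 1.45-fold in WT and 3.38-fold in Mcl1KO (interaction -1.22, adjusted p = 0.0163), where the call in WT was lost without fed WT replicate 1, 3 or 5 or fasted WT replicate 4 (adjusted p up to 0.0829). Nlrp12 rose 1.77-fold in WT, a call lost without fed WT replicate 1, 3 or 4 or fasted WT replicate 1 or 5 (adjusted p up to 0.0953), and 7.19-fold in Mcl1KO (interaction 2.02, adjusted p = 0.00842). Msrb3, a methionine sulfoxide reductase gene, rose 1.91-fold in Mcl1KO and measured log2 -0.31 in WT, while Ropn1l fell 1.80-fold in Mcl1KO and measured 0.44 in WT (interaction 1.25 and -1.29, adjusted p = 0.00842 for both). Hyou1, a chaperone of the endoplasmic reticulum, fell 1.64-fold in Mcl1KO and measured 0.33 in WT (interaction -1.04, adjusted p = 0.022). The Kupffer marker Vsig4 fell 1.92-fold in WT and measured 0.32 in Mcl1KO (interaction 1.26, adjusted p = 0.022). Tbc1d15, a regulator of small GTPases, had an interaction of 1.15 (adjusted p = 0.022).

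**Figure D2:**
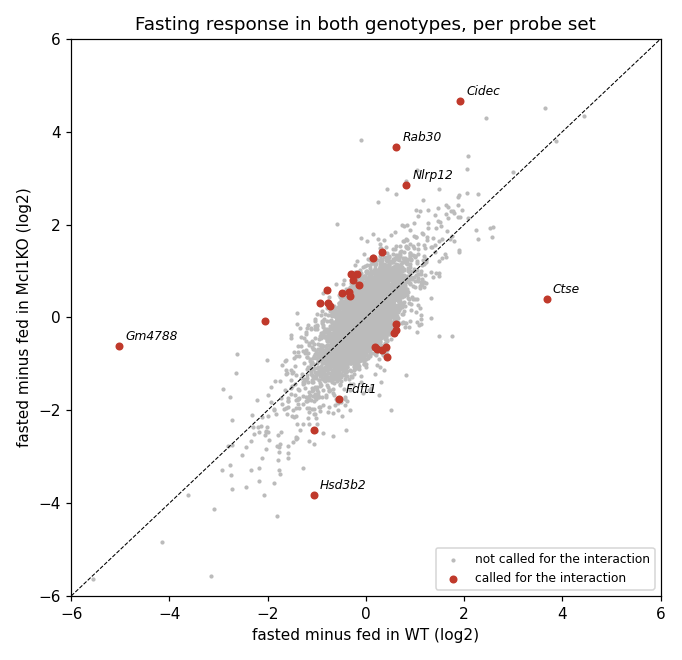
Fasted minus fed difference (log2) in WT (horizontal) and in Mcl1KO livers (vertical), 1 point per probe set, with the 30 probe sets called for the interaction in red and the line of equal response dashed. The differences correlate at r = 0.68 across probe sets, and Cidec, Rab30 and Nlrp12 lie above the line while Hsd3b2 and Fdft1 lie below it.

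Limma called 30 probe sets for the interaction, 18 higher and 12 lower, and 2477 had an unadjusted p under 0.05 where chance gives 1110. After quantile normalisation of the deposited values the split was 17 higher and 18 lower, and after median centring 27 and 11. Calls also depended on single arrays. Without fasted Mcl1KO replicate 3 the count was 331 and without fasted Mcl1KO replicate 4 it was 62. It was 9 without fasted WT replicate 2, 13 without fasted Mcl1KO replicate 5, 15 without fed WT replicate 5, 18 without fasted WT replicate 3 and 19 without fed WT replicate 2. It was 17 without fed Mcl1KO replicate 3, fed Mcl1KO replicate 5 or fasted Mcl1KO replicate 2. Of the 18 called genes named here 7 kept the call whichever array was left out, namely Hsd3b2, Rab30, Nlrp12, Msrb3, Ropn1l, Fdft1 and Gm4788. An ordinary model without moderation called 3 probe sets, and of the 18 genes it kept Hsd3b2. The other 6 of these 7 reached adjusted p of 0.115, 0.0674, 0.0604, 0.0604, 0.0674 and 0.0674 at most over their alternatives. Trend and robust moderation also ended the calls of Rab30, Cidec and Ctse. The call of Cidec was lost without fasted WT replicate 2, those of Tbc1d15 and Hyou1 without that array or fasted Mcl1KO replicate 5, and that of Vsig4 without either of these or fed WT replicate 5. Across all alternatives these 4 reached adjusted p of 0.122, 0.0674, 0.0674 and 0.0854. Rab31, Csnk1e, Fcna, Ddx28, Apol9a and Timm17a lost theirs in 16, 16, 17, 18, 12 and 12 of the 20 fits. Ctse, an aspartic protease gene, rose 12.9-fold in WT (log2 3.68, and 4.39 without fed WT replicate 1) and measured 1.32-fold in Mcl1KO (interaction -3.29, SE 0.65, adjusted p = 0.0382). Its call was lost in 15 of the 20 fits, and its signal in fed WT replicate 1 was 6.54 against 2.70 to 3.25 in the other fed WT livers, without which the interaction was -4.0. Gm4788, a gene outside the naming rule and chosen after its values were seen, fell 32.7-fold in WT (log2 -5.03, and -5.76 without fed WT replicate 1; interaction 4.41, adjusted p = 0.00842), with 6.0 in fed WT replicate 1 against 9.62 to 9.74 in the others and an interaction of 5.15 without that array.

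As groups, cholesterol synthesis genes fell further in Mcl1KO than in WT (median interaction log2 -1.01, 1 of 19 members called lower, 15 adjusted over the list alone; camera adjusted p = 3.38e-15, and adjusted p = 0.164 with an estimated correlation). This list was also called between the fed genotypes (camera adjusted p = 0.00871), a call lost without fed WT replicate 2 (adjusted p = 0.642). Part of its interaction may therefore lie in the fed livers. PPARα targets had a median of 0.65 (1 of 24 called higher, 7 adjusted over the list alone; adjusted p = 3.45e-09, and adjusted p = 0.228 with an estimated correlation). For Sqle the interaction was -2.49 (adjusted p = 0.0502) and for the peroxisomal gene Ehhadh 1.24 (adjusted p = 0.0607), both short of the threshold. Lipid droplet genes were the 1 list that kept its call with an estimated correlation (adjusted p = 0.0450; preset adjusted p = 0.00097; 1 of 22 called, 6 adjusted over the list alone). Ribosome biogenesis had 0 of 28 called and 5 adjusted over the list alone (median 0.31; adjusted p = 1.45e-06, and adjusted p = 0.203 with an estimated correlation). Among marker lists, endothelial markers had a median of 0.55 (0 of 17 called, 5 adjusted over the list alone; adjusted p = 1.95e-07, and adjusted p = 0.164 with an estimated correlation). Kupffer cell markers had one of 0.42 (1 of 16 called, 1 adjusted over the list alone; adjusted p = 0.000223, and adjusted p = 0.237 with an estimated correlation). Hepatocyte, lymphocyte and bile duct markers were not called as lists (adjusted p = 0.600, 0.261 and 0.624), with 0 members called over all genes or adjusted over the list alone. In total 22 of 46 lists were called, and 9 with fry.

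With food, few probe sets passed the test between genotypes. Limma called 8 probe sets, 5 higher and 3 lower, one of which is Mcl1 itself, and 1429 had an unadjusted p under 0.05 where chance gives 1110. WT and Mcl1KO arrays did not overlap in 349 probe sets (1.57%, against 0.794% by chance). Asic5, an acid-sensing ion channel gene, was 6.62-fold higher in Mcl1KO (log2 2.73, SE 0.21, adjusted p = 1.11e-07). Mme, which encodes the peptidase neprilysin, was 10.8-fold lower (log2 -3.43, SE 0.35, adjusted p = 9.82e-06), although fed Mcl1KO replicate 4 had 5.28 against 2.59 to 2.77 in the others. Insc was 2.41-fold higher (adjusted p = 0.0021), with 2.57 in fed WT replicate 1 against 2.91 to 3.0 in the others. Mmp12, a macrophage elastase gene, was 8.81-fold higher (log2 3.14, SE 0.51, adjusted p = 0.0108), a call lost with the ordinary model and with trend and robust moderation (adjusted p up to 0.157). Mad2l1, of the spindle checkpoint, and Trim2 were 2.11-fold and 1.94-fold higher (adjusted p = 0.0112 and 0.0108). Both calls were lost without fed WT replicate 4, with the ordinary model and in a fit of the 10 fed arrays alone (up to 0.141 and 0.121). Selenbp2 was 3.71-fold lower (adjusted p = 0.0112), and its call was lost under these 2 models, with trend and robust moderation and without fed Mcl1KO replicate 3 or 5 (up to 0.157). Asic5, Mme, Selenbp2 and Trim2 lie on the chromosome of Mcl1. The count rose to 15 without fed WT replicate 1, to 13 without fed Mcl1KO replicate 2 and to 16 without fed Mcl1KO replicate 4. It was 26 with array weights and 49 in a fit of the 10 fed arrays alone with trend and robust moderation, the latter chosen after seeing the data.

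No list had more than 1 member called in the fed comparison, though camera called 14 of 46 lists. The interferon response had a median of 0.16 (0 of 23 called, 5 higher adjusted over the list alone; adjusted p = 3.28e-06) and was the 1 list that kept its call with an estimated correlation (adjusted p = 0.0436). Cell cycle genes had a median of 0.27 (0 of 30 called over all genes or adjusted over the list alone; adjusted p = 1.81e-08, and adjusted p = 0.0523 with an estimated correlation), with Mcm6 at 0.75 and Ccnb2 at 0.73 on the log2 scale. Fed Mcl1KO replicate 2 had 5.37 for Mcm6 (3.05 to 4.45 in the others) and 5.92 for Ccnb2 (3.73 to 5.03), and without it both stood at 0.41. Endoplasmic reticulum chaperones had a median of 0.16 (0 of 20 called, 4 adjusted over the list alone; adjusted p = 3.28e-06, and adjusted p = 0.140 with an estimated correlation), with Creld2 at 0.68 and Hyou1 at 0.63. Acute phase genes had one of 0.18 (0 of 24 called, 5 higher and 1 lower adjusted over the list alone; adjusted p = 2.11e-05, and adjusted p = 0.245 with an estimated correlation), where Lcn2 was at 2.33 and Saa2 at 1.94 (adjusted p = 0.108 and 0.109). De novo lipogenesis had one of -0.19 (0 of 20 called, 4 lower adjusted over the list alone; adjusted p = 2.27e-05, and adjusted p = 0.140 with an estimated correlation). Endothelial markers had one of -0.27 (0 of 17 called, 4 lower adjusted over the list alone; adjusted p = 2.32e-05, and adjusted p = 0.198 with an estimated correlation). Stellate cell markers had a median of 0.16 (0 of 22 called, 2 higher and 1 lower adjusted over the list alone; adjusted p = 0.0035, and adjusted p = 0.198 with an estimated correlation), a list call lost without fed WT replicate 2 (adjusted p = 0.052) or fed Mcl1KO replicate 2 (adjusted p = 0.0586). Infiltrating myeloid markers had 1 of 18 higher, Mmp12 (1 adjusted over the list alone; adjusted p = 0.024, and adjusted p = 0.198 with an estimated correlation). That list call was lost without fed WT replicate 1 (adjusted p = 0.104) or 2 (0.0606) or fed Mcl1KO replicate 1 (0.104), 2 (0.0921) or 5 (0.0719). Genes of the integrated stress response were not called as a list (adjusted p = 0.371), although Atf3 stood at 2.29 (SE 0.79, adjusted p = 0.561, and 3.04 without fed Mcl1KO replicate 4). The BCL2 family, with 0 of 20 called over all genes or adjusted over the list alone, had an adjusted p of 0.947.

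In the fast, many more probe sets passed the test between genotypes than with food. Counts at a threshold do not test whether the genotype difference depends on feeding. The interaction contrast tests this, and it called 30 probe sets. Asic5 was 11.7-fold higher (log2 3.55, SE 0.21, adjusted p = 4.69e-10), as it was with food. Lepr was 11.5-fold higher (SE of log2 0.66, adjusted p = 0.0035), Cidec 6.95-fold (SE 0.35, adjusted p = 8.44e-05), the tubulin gene Tubb2a 5.79-fold, the drug-inducible cytochrome gene Cyp2b10 5.22-fold, and Pdk4, which limits glucose oxidation, 4.56-fold. Ddit4, an inhibitor of mTOR signalling, was 3.90-fold higher (adjusted p = 0.00873), Ly6d 3.95-fold and Nlrp12 4.04-fold. Lepr had 7.93, 9.19, 4.69, 4.33 and 8.68 in fasted Mcl1KO replicates 1 to 5 against 2.79 to 4.32 in fasted WT livers, and its log2 difference of 3.53 was 4.19 without replicate 4. In the same 5 arrays Pdk4 had 7.97, 8.93, 6.03, 6.18 and 7.54 and Ddit4 8.27, 8.02, 6.4, 6.62 and 8.87. Ctse was 19.7-fold lower (log2 -4.30, SE 0.46, adjusted p = 7.43e-06) and Gm4788 was 32.5-fold higher. Car3, the succinate receptor gene Sucnr1, Inmt, Hsd3b3 and Hsd3b2 were lower by 6.41-fold, 6.35-fold, 5.41-fold, 5.13-fold and 4.08-fold. Of the 10 largest falls that the naming rule took here, Car3, Sucnr1, Hsd3b3, Hsd3b2, Car1 and Mme lie on the chromosome of Mcl1, Hsd3b2 and Hsd3b3 within 200 measured genes of it. Slc22a28, Car1 and Pm20d1 were lower by 3.28-fold, 3.25-fold and 3.13-fold. Limma called 1109 probe sets, 738 higher and 371 lower, of which 158 differed at least 2-fold. Repeated quantile normalisation gave 561 higher and 459 lower, and median centring 880 and 272. The count was 722 without fasted WT replicate 4, and 647, 497 and 646 without fasted Mcl1KO replicates 1, 2 and 5. It was 1707 without fasted Mcl1KO replicate 3, 700 with the ordinary model and 399 in a fit of the 10 fasted arrays alone. WT and Mcl1KO arrays did not overlap in 866 probe sets (3.90%, against 0.794% by chance). Of the 8 probe sets called with food, 3 were also called in the fast, 1 higher and 2 lower, where independent lists share 0.166 and 0.0501. Across probe sets the fold changes in the 2 feeding states correlated at r = 0.18.

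Cholesterol synthesis genes were lower in fasted Mcl1KO than in fasted WT livers, with 10 of 19 called lower and 0 higher (15 lower adjusted over the list alone; camera adjusted p = 2.41e-12, and adjusted p = 0.126 with an estimated correlation). Sqle was 3.39-fold, Idi1 2.57-fold and Fdft1 2.06-fold lower. Ribosome biogenesis genes had 8 of 28 higher (17 adjusted over the list alone; adjusted p = 2.43e-11, and adjusted p = 0.116 with an estimated correlation), with Nop58 at 2.26-fold and Ddx21 at 1.91-fold. PPARα targets had 7 of 24 higher (10 adjusted over the list alone; adjusted p = 1.40e-08, and adjusted p = 0.210 with an estimated correlation). Cpt1a (1.16-fold, adjusted p = 0.306) and Cyp4a14 (1.08-fold, adjusted p = 0.957) were not called. Cyp4a14 in fasted livers lay at 11.59 to 11.95, near the highest value on any array (12.56), where a difference may not show. Peroxisomal beta-oxidation had 4 of 20 higher (7 adjusted over the list alone; adjusted p = 0.000423, and adjusted p = 0.285 with an estimated correlation), with Ehhadh at 2.24-fold. Lipid droplet genes had 5 of 22 higher (9 higher and 2 lower adjusted over the list alone; adjusted p = 0.00908, and adjusted p = 0.116 with an estimated correlation), with the droplet coat gene Plin2 at 2.25-fold. The mitochondrial unfolded protein response had 5 of 14 higher (5 adjusted over the list alone; adjusted p = 1.59e-05, and adjusted p = 0.12 with an estimated correlation), with Timm17a, an import subunit gene that lies near Ctse on its chromosome, at 2.22-fold and Clpx at 1.59-fold. The citric acid cycle had 4 of 18 higher (4 adjusted over the list alone; adjusted p = 0.000161, and adjusted p = 0.235 with an estimated correlation), with the citrate synthase gene Cs at 1.57-fold.

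Of the other members of Mcl1's own family, 2 of 20 were called higher in the fast (2 adjusted over the list alone; list adjusted p = 0.291). They are Bcl2l1, the gene of the anti-apoptotic protein BCL-XL, at 2.19-fold (SE of log2 0.22, adjusted p = 0.00524) and the mitophagy receptor gene Bnip3l at 1.60-fold (adjusted p = 0.00167). Clock genes had 1 of 18 higher and 5 lower (1 and 7 adjusted over the list alone; adjusted p = 0.0205, and adjusted p = 0.235 with an estimated correlation), with Dbp 3.71-fold and Per3 2.70-fold lower. That list call was lost without fasted Mcl1KO replicate 4 (adjusted p = 0.110) or 5 (adjusted p = 0.0516). Genes regulated by p53 had 2 of 23 higher (3 adjusted over the list alone; adjusted p = 0.0205, and adjusted p = 0.12 with an estimated correlation), with Sesn1 at 3.37-fold (not called in the fit of the fasted arrays alone), a list call lost without fasted Mcl1KO replicate 4 (adjusted p = 0.0674) or 1 (adjusted p = 0.0516). Sesn1 had 7.76, 7.90, 5.59, 5.74 and 8.68 in fasted Mcl1KO replicates 1 to 5 against 5.16 to 5.60 in fasted WT livers. Kupffer cell markers had 7 of 16 higher and 0 lower (11 higher adjusted over the list alone; adjusted p = 1.47e-08, and adjusted p = 0.119 with an estimated correlation). Vsig4 was 2.33-fold, Lyz2 1.93-fold, a call lost in the fit of the fasted arrays alone, and the complement gene C1qc 1.73-fold higher. Infiltrating myeloid markers had 3 of 18 higher (6 adjusted over the list alone; adjusted p = 0.0019, and adjusted p = 0.119 with an estimated correlation), with Cd9 at 2.19-fold. Endothelial markers had 0 of 17 called and 3 higher adjusted over the list alone (adjusted p = 0.0019, and adjusted p = 0.285 with an estimated correlation). Hepatocyte markers had 0 higher and 2 lower of 18 (1 and 2 adjusted over the list alone; adjusted p = 0.314), lymphocyte and bile duct markers 0 called over all genes or adjusted over the list alone. In total 25 of 46 lists were called, 0 of them with an estimated correlation, 22 on ranks and 18 with fry.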

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

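For the pattern around Ctse, the tests of its window and of a wrong label were chosen only after the result was seen. The rule of the test on window genes that were not called was fixed before its value was seen. Its window and array, however, were picked from the pattern. The counts over other splits of the arrays were planned beforehand. An array is listed here when its gap to the nearest array of its group exceeds Dixon's 95% critical value, which chance does in about 1 of 20 groups. This held in 42 of 492 groups, where chance gives 24.6.

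Fed WT replicate 1 stood with the fasted WT livers for a few genes. Its log2 signal was 6.54 for Ctse against 2.70 to 3.25 in the other fed WT livers, and 6.0 for Gm4788 against 9.62 to 9.74. Of the 28 genes called for the interaction, 4 (Ctse, Gm4788, Timm17a and Tor3a, the last a gene outside the naming rule and chosen after its values were seen) lie within 200 measured genes of Ctse on its chromosome, and without Ctse it is 3 of 27 (one-sided Fisher's exact p = 0.0174). That p is no independent evidence, since the window was centred on Ctse for its pattern and Gm4788, which shares the pattern, is among the 3. A fasted liver with a wrong label is argued against, because over 326 probe sets changed at least 2-fold by fasting in WT and outside that window the array's median position was 0.0157, where 0 is the mean of the other fed WT arrays and 1 that of fasted WT arrays. Across 397 window genes not called for the interaction, its deviation from the other fed WT arrays correlated with that of fasted WT at r = 0.435, and 1 of 225 other windows was as high (highest 0.442, median 0.261), where genes are not independent and both deviations share the other fed WT arrays in every window. Neighbouring windows also share most of their genes, so the 225 are not independent, and 1 of 225 overstates how rare such a correlation is. A DNA segment carried by fasted WT mice and this mouse but not by the other fed WT mice may lie behind the calls near Ctse, which stays a hypothesis since genotypes at this segment are not given in the sources used here.

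In fed WT livers, other single arrays stood apart as follows. Replicate 1 had 8.04 for Cyp4a14 (9.93 to 10.2 in the others), 7.54 for Acadm (7.73 to 7.79), 2.57 for Insc (2.91 to 3.0), 6.86 for Pm20d1 (5.80 to 6.06) and 7.43 for Bnip3l (7.55 to 7.60). Replicate 2 had 3.71 for Slc27a1 (4.50 to 4.59), 3.47 for Cidec (2.75 to 2.93) and 6.91 for Rab30 (5.08 to 5.52). Replicate 3 had 6.99 for Cyp17a1 (4.56 to 5.26), and replicate 5 had 7.96 for Slc25a20 (7.71 to 7.77).

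Among fasted WT livers, replicate 4 had 9.37 for Cpt1a (9.70 to 9.81 in the others), 7.76 for Slc25a20 (8.68 to 8.82), 5.0 for Nsdhl (7.03 to 7.63), 6.72 for Sucnr1 (7.60 to 7.84) and 9.22 for Hadhb (9.57 to 9.68). Replicate 1 had 8.67 for Cyp1a2 (7.45 to 7.73), 9.47 for Dbp (9.0 to 9.12), and 6.42 and 5.24 for the pancreatic genes Amy2a5 (3.58 to 3.87) and Ctrb1 (2.56 to 3.17). Replicate 5 had 6.28 for Hsd3b2 (6.97 to 7.12) and 5.78 for Tbc1d15 (5.08 to 5.21), and replicate 2 had 3.74 for Csnk1e (4.19 to 4.37).

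Fed Mcl1KO replicate 2 had 10.34 for Apoa4 (8.17 to 8.67 in the others), 7.01 for Ppargc1a (5.67 to 5.95), 8.60 for Hsd3b5 (9.60 to 9.85), 5.78 for Mki67 (3.26 to 3.66) and 5.41 for Col3a1 (3.88 to 4.25). Replicate 4 of that group had 5.28 for Mme (2.59 to 2.77), 5.44 for Bcl2l1 (5.89 to 6.04) and 7.34 for Cs (7.13 to 7.18). Its replicate 1 had 7.31 for Acadm (7.63 to 7.68), 8.74 for Hadhb (9.06 to 9.15) and 6.60 for Slco1a4 (7.37 to 7.61), and its replicate 3 had 2.54 for Slc16a6 (2.84 to 2.90) and 3.95 for Ddx28 (4.34 to 4.49). In fasted Mcl1KO livers, replicate 4 had 7.49 for Zbtb16 (8.42 to 8.56), replicate 3 had 4.14 for Sqle (2.51 to 2.89), replicate 2 had 6.25 for Rab31 (5.0 to 5.36) and 6.36 for Pkm (5.35 to 5.55), and replicate 5 had 3.72 for Ctrb1 (2.37 to 2.60).

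The fasting response differed between genotypes by the interaction contrast in 19 named genes. The log2 differences were 4.41 for Gm4788, 3.04 for Rab30, 2.74 for Cidec, 2.02 for Nlrp12, 1.37 for Rab31, 1.26 for Vsig4, 1.25 for Msrb3, 1.15 for Tbc1d15, 1.11 for Csnk1e, 1.09 for both Fcna and Ddx28, 1.07 for Tor3a and 0.88 for Timm17a. They were -3.29 for Ctse, -2.77 for Hsd3b2, -1.38 for Apol9a, -1.29 for Ropn1l, -1.22 for Fdft1 and -1.04 for Hyou1. The call of Tor3a was lost in 10 of the 20 fits that leave out 1 array and with the ordinary model (adjusted p up to 0.0878). The limits of the other calls are those given beside the interaction result.

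By camera at its preset correlation, 22 lists also differed. The median log2 interaction was 0.65 for PPARα targets, 0.55 for endothelial and 0.42 for Kupffer cell markers, 0.31 for ribosome biogenesis, 0.23 for the mitochondrial unfolded protein response, 0.22 for both glycolysis and peroxisomal beta-oxidation, 0.20 for the citric acid cycle, 0.18 for both mitochondrial beta-oxidation and complex I, 0.17 for mitochondrial dynamics, 0.16 for both complexes II to V and lipid droplets, and 0.089 for autophagy and lysosomes. It was -1.01 for cholesterol synthesis, -0.25 for both cell cycle and male-biased genes, -0.21 for chaperones of the endoplasmic reticulum, -0.20 for pericentral hepatocyte genes, -0.19 for the interferon response, -0.16 for xenobiotic cytochromes and -0.10 for the acute phase. Of these 22 lists, 1 (lipid droplets) kept its call with an estimated correlation. With 1 array left out, 7 of the 22 lost theirs in some fits. Mitochondrial beta-oxidation did without fasted WT replicate 4 (adjusted p = 0.176) or fed Mcl1KO replicate 1 (0.0652), and male-biased genes without fasted Mcl1KO replicate 4 (0.172). Pericentral genes did without fasted WT replicate 1 (0.052) or fed Mcl1KO replicate 5 (0.0547). The acute phase did without fed WT replicate 1 (0.0693) or 4 (0.0551), fasted WT replicate 4 (0.0584) or fed Mcl1KO replicate 1 (0.0978) or 4 (0.147). Xenobiotic cytochromes did without fed WT replicate 1 (0.0764), fed Mcl1KO replicate 4 (0.0581) or 5 (0.0612) or fasted Mcl1KO replicate 2 (0.0992). Mitochondrial dynamics did without fasted WT replicate 4 (0.0706), fed Mcl1KO replicate 1 (0.0889) or fasted Mcl1KO replicate 1 (0.0613) or 4 (0.0963). Autophagy and lysosomes did without fed WT replicate 2 (0.0556) or 3 (0.0689), fasted WT replicate 4 (0.0863), fed Mcl1KO replicate 1 (0.0761) or fasted Mcl1KO replicate 1 (0.0613) or 5 (0.0592).

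For each count of probe sets and of lists, under 5% of 100 splits, the real one included, reached the real value. The other splits mix the compared groups, which puts a real difference into their spread. For the pairwise contrasts, each also leaves unequal numbers of the compared groups on its 2 sides, so part of a real difference stays between these. The counts of the other splits therefore cannot exclude chance and are no rate of false calls. For fasting in WT 1 split gave as many as the 1507 probe sets (highest other 46) and 1 as many as the 28 lists (highest other 23). For fasting in Mcl1KO 1 split gave 3208 probe sets (highest other 1066) and 1 gave 31 lists (highest other 30). For the fasted comparison of genotypes 1 gave 1109 (highest other 614) and 1 gave 25 lists (highest other 22). For the interaction 1 gave 30 (highest other 13) and 1 gave 22 lists (highest other 21). For the fed comparison 2 splits gave as many as the 8 probe sets, the other calling 10, and 1 gave 14 lists (highest other 13).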

How the results depend on the processing

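Chosen only after the data were seen were the fits without pairs of fasted Mcl1KO arrays, without neighbours of Mcl1, of the fed arrays alone with trend and robust moderation, and the lists after rescaling. Of 337 gene results, 256 kept their direction and side of the threshold under every alternative, 58 fell below the threshold under at least 1, 21 passed it under at least 1, and 2 turned. For changes below, the cause was not tested, except that a required fold lowers a count by construction. Leaving out arrays lowered some counts and raised others.

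With a required 2-fold change the counts were 336 for fasting in WT, 668 for fasting in Mcl1KO, 158 for the fasted comparison and 254 for calls shared by the fasting contrasts. Tested against 1.2-fold (treat) they were 437, 1212, 73, 5 for the fed comparison and 4 for the interaction. The ordinary model gave 4 in the fed comparison, 700 in the fasted and 3 in the interaction. Trend and robust moderation gave 15 in the fed comparison and 5 calls shared by the feeding states, and array weights gave 26 in the fed comparison and 55 in the interaction. A fit of the compared groups alone gave 399 in the fasted comparison, and with trend and robust moderation 49 in the fed. Without genes within 200 of Mcl1 the counts were 6 and 1080. Lists called with an estimated correlation were 6, 11, 1, 0 and 1 for fasting in WT, fasting in Mcl1KO, fed, fasted and interaction, and fry called 3 in the fed comparison and 9 in the interaction. Both rescalings left each list count within 1.5 times and turned no called list.

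Leaving out each array in turn gave 1124 to 1580 calls for fasting in WT, 2689 to 3418 for fasting in Mcl1KO, 7 to 16 in the fed comparison, 497 (without fasted Mcl1KO replicate 2) to 1707 (without replicate 3) in the fasted, 9 (without fasted WT replicate 2) to 331 (without fasted Mcl1KO replicate 3) in the interaction, and 3 to 6 calls shared by the feeding states. The uncalled fasting difference of Mcl1 in Mcl1KO ranged from -0.037 to 0.12, and that of Amy2a5 in the interaction from -0.64 to 0.065, which turned without fasted WT replicate 1. Without 2 fasted Mcl1KO arrays, fasting in Mcl1KO had 2093 (without 1 and 2), 2123 (1 and 5) and 2117 (2 and 5) calls. The fasted comparison had 167 (1 and 2), 496 (1 and 4), 383 (1 and 5), 345 (2 and 4), 179 (2 and 5), 1989 (3 and 4) and 478 (4 and 5). The interaction had 8 (1 and 2), 301 (1 and 3), 17 (1 and 4), 11 (1 and 5), 169 (2 and 3), 10 (2 and 4), 3 (2 and 5), 765 (3 and 4), 223 (3 and 5) and 3 (4 and 5).

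No pairing of arrays by replicate number was detected. Same-numbered arrays deviated together at a mean r of -0.022 (-0.19 to 0.17), over 0.1 in 1 of 30 pairs. The labels do not state whether the numbers pair the mice. With the replicate block the counts were 1375, 3045, 8, 924 and 20, in the order above. Signal over background limits the folds of genes with a low mean in 1 group, such as Nlrp12 (2.10 in fed WT) and Mme (2.39 in fasted Mcl1KO), which RMA compresses.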

Other observations

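Some genes of hormone signalling and sex-biased expression passed the test for fasting. Of 14 genes with male-biased expression in mouse liver 6 fell in WT (9 adjusted over the list alone; camera adjusted p = 3.50e-13, and adjusted p = 0.0402 with an estimated correlation) and 10 in Mcl1KO livers (11 adjusted over the list alone; adjusted p = 1.97e-14, and adjusted p = 0.0295 with an estimated correlation), with Nudt7 at -2.53 and -2.96 on the log2 scale. Another probe set of Nudt7 was not called in WT (-0.72, adjusted p = 0.0546). In the insulin and growth hormone axis 5 of 16 genes rose and 5 fell in fasted Mcl1KO livers (5 and 5 adjusted over the list alone; list adjusted p = 0.363), where the growth hormone receptor gene Ghr changed by -1.34, Igfals by -1.51 and Socs2, an inhibitor of cytokine signalling, by 2.0. Bile acid synthesis and transport had 4 of 23 higher and 10 lower in Mcl1KO livers (5 and 10 adjusted over the list alone; adjusted p = 0.123), with the sterol hydroxylase gene Cyp8b1 at 2.59, the transporter gene Slco1a4 at 2.28 and Nr0b2, a repressor of bile acid synthesis, at -1.56.

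NRF2 targets had 0 of 21 higher and 6 lower in fasted WT (2 and 8 adjusted over the list alone; adjusted p = 0.000163, and adjusted p = 0.250 with an estimated correlation), led by the glutathione transferase gene Gstm3 at -2.27. Autophagy and lysosome genes had 4 of 27 higher in fasted Mcl1KO against fasted WT (6 adjusted over the list alone; adjusted p = 0.0048, and adjusted p = 0.12 with an estimated correlation), including Wipi1 at 0.88 and the cathepsin gene Ctsl at 0.61. Neither gene was called in a fit of the fasted arrays alone (adjusted p = 0.0911 and 0.0835), nor Ctsl without fasted Mcl1KO replicate 2 (adjusted p = 0.0525). Glycolysis had 2 of 15 higher in the same comparison (6 adjusted over the list alone; adjusted p = 0.00205, and adjusted p = 0.12 with an estimated correlation), Pkm at 0.65 and Ldha at 0.49. Neither was called in a fit of the fasted arrays alone (adjusted p = 0.0929 and 0.129). The call of Pkm was also lost without fasted WT replicate 1 (adjusted p = 0.0619) or 2 (0.068) or fasted Mcl1KO replicate 2 (0.0698). That of Ldha was lost without fasted WT replicate 2 (0.0515), 3 (0.0672) or 4 (0.0918) or fasted Mcl1KO replicate 2 (0.0912) or 4 (0.0681). Stellate cell markers had 4 of 22 lower in fasted WT (4 adjusted over the list alone; adjusted p = 0.00805, and adjusted p = 0.180 with an estimated correlation), with the collagen gene Col3a1 at -1.01. Exocrine pancreas markers had a median of -0.21 between the fasted genotypes (0 of 13 called over all genes or adjusted over the list alone; adjusted p = 0.0148, and adjusted p = 0.391 with an estimated correlation), a call lost without fasted WT replicate 1 (adjusted p = 0.356) or fasted Mcl1KO replicate 4 (adjusted p = 0.0609).

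In the 2 patterns that follow, the tests of position near Mcl1 and of the clock were chosen only after the result was seen, and the test of scaling was not.

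Some genotype calls lie near Mcl1, where DNA from the strain of the targeted stem cells can stay linked to the floxed allele: of 7 fed calls other than Mcl1, 4 are on its chromosome against 4.71% of genes (one-sided Fisher's exact p = 0.000153), but 1, Selenbp2, is within 200 measured genes of it (p = 0.135), which leaves linked DNA open for the fed calls. In the fast 949 of 1002 calls that were not called with food lie on other chromosomes, where 50.1 false calls are allowed, so genes in linked DNA cannot be all of the fasted calls, while effects of linked DNA on genes elsewhere were not tested. The window held 24 of the 1002 (2.40%, one-sided Fisher's exact p = 0.244) and the chromosome 53 (5.29%, p = 0.207). Of the calls for fasting in WT, the window held 3.14% and the chromosome 6.51%, where 2.05% and 4.71% of genes lie (one-sided Fisher's exact p = 0.00348 and 0.00116). Both groups of that contrast are labelled WT. The segment proposed near Ctse lies on another chromosome than Mcl1, so its own genes add nothing to these shares. Whether fed and fasted WT mice also differ in DNA near Mcl1 is not given in the sources used here. The calls for fasting in WT are therefore no sure baseline free of genotype. Of the 10 largest fasted falls, 6 are on the chromosome of Mcl1, 2 of them in its window. For fasting in WT and for fasting in Mcl1KO, 3 of the 10 largest falls each are on that chromosome. No group carries the floxed allele without Cre by its label, so linked DNA and a response to the loss of Mcl1 cannot be told apart for these falls or the fed calls.

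Fasted Mcl1KO livers lay on average further along the fasting response than fasted WT livers. The score, which is the mean log2 change in the direction of fasting, relative to the mean of fed livers, over 3715 probe sets called for fasting averaged over genotypes, was 0.495 ± 0.049 (SD, n = 5) in fasted WT and 0.71 ± 0.116 in fasted Mcl1KO livers (difference 0.214, two-sided exact permutation p = 0.0159 over 252 regroupings), with 0.783, 0.801, 0.546, 0.627 and 0.791 in the 5 Mcl1KO arrays against 0.427 to 0.562 in fasted WT, so that replicate 3 lay within the WT range. After either rescaling the difference was 0.206 or 0.217, both with an exact p of 0.0159. A shift common to an array largely cancels in a score of rising and falling genes, and RMA had already equalised the arrays. The test therefore cannot exclude scaling of the arrays. Dbp, a clock output gene, differed by -1.89 between the fasted genotypes, with 6.36, 6.52, 9.01, 8.10 and 6.18 in the same 5 arrays against 9.0 to 9.47 in fasted WT, which a different time of day at harvest and a response to the loss of Mcl1 both allow. A larger response to fasting without Mcl1 is therefore a hypothesis, and the Mcl1 signals of the same arrays (6.18, 6.19, 5.88, 5.94 and 6.50) decide nothing here because the exons measured are unknown, with the harvest time and the treatment of WT mice not given in the sources used here.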
